A study of Drosophila melanogaster with 72 samples.

How the data were processed

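The material was whole males of Drosophila melanogaster, 3 to 5 days old, carrying 1 of 6 mitochondrial haplogroups and 1 of 6 Y haplotypes from the Global Diversity Lines, a panel of inbred lines from several populations. The mitochondrial haplogroups were B38 and B39 from Beijing, I02 from Ithaca, and N01, N02 and N23 from the Netherlands. The Y haplotypes were B04 and B11 from Beijing, N03 and N07 from the Netherlands, and ZH23 and ZW139 from Zimbabwe. Mothers from mitochondrial replacement lines were crossed with fathers from Y replacement lines, both kinds of line described by the submitters as sharing a single nuclear background. A son takes his mitochondria and X chromosome from the mother, his Y from the father, and his autosomes from both. Each of the 36 combinations had 2 libraries, each from a pool of 10 males and from its own cross, so that every haplotype was represented by 12 of the 72 libraries. Per the labels, the 18 second replicates of N01, N02 and N23 formed batch 2 and the other 54 libraries batch 1.

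RNA was extracted with Trizol and sequenced from libraries of the Lexogen QuantSeq 3' FWD kit, which reads the 3' end of polyadenylated transcripts, so that counts were not corrected for gene length. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.36, STAR 2.6, HTSeq 0.11.0 and DESeq2 without a version. The genome build and gene annotation behind the alignment are not given in the sources used here. The values used are the raw counts of reads per gene that the authors deposited, in 1 table for the series and in 1 file per library. All 72 columns of the table were identical to the files of the single libraries, which also hold counts of reads aligned to several places, to no gene or to more than 1 gene. A deposited table of normalized values was not used here, because each of its columns is the raw count divided by 1 constant. The table has 17324 features, of which 17037 have a symbol in the Ensembl 115 annotation of assembly BDGP6.54 and in the FlyBase names that go with it; coordinates given for genes come from that annotation by gene identifier. The series text writes 2 of the Y haplotypes in another way than the sample labels, and the names of the labels are used.

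Counts in genes ranged from 2454024 to 7671784 per library, with a median of 4792638, 4976817 in batch 1 and 4370605 in batch 2. Between 13436 and 14401 genes were detected per library. The variance between the 2 libraries of a combination was 11.4 to 110 times that of sampling noise, as chi-square per degree of freedom over 10464 genes together. Intervals for single libraries are Wilson intervals at 95% and cover counting error only, since reads of a gene without molecular identifiers are not independent molecules. The correlation of log2 CPM, counts scaled by library size, between the 2 libraries of a combination, across genes, was 0.877 to 0.982 with a median of 0.954, and 3 of 72 libraries had their own partner as the closest library.

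Genes were kept by filterByExpr of edgeR 4.0.16 over the 36 groups, which left 12470 genes holding 99.9% of the counts. With TMM normalization, a negative binomial model with mitochondrial haplogroup, Y haplotype, their interaction and batch was fitted to all 72 libraries by the quasi-likelihood method of edgeR in R 4.3.3. This left 35 residual degrees of freedom, a median of 6.78 prior degrees of freedom and a biological coefficient of variation of 0.285. F tests were run for the haplogroup, the Y haplotype and the interaction. Single contrasts compared each haplotype with the unweighted mean of the other 5, averaged over the other factor. Further contrasts compared mitochondria from Beijing with those from the Netherlands, Y chromosomes from Beijing with those from the Netherlands, Y chromosomes from Zimbabwe with the other Y chromosomes, and same-population with mixed-population pairs of Beijing and the Netherlands. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All p-values are 2-sided and adjusted over all 12470 genes unless stated otherwise. Log2 fold changes are given with the standard error implied by the F statistic, and group levels as mean CPM with the SD over 12 libraries.

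The design, tests, 31 gene lists, rule for named genes and most alternatives were set before the data were examined. The rule names, for each haplotype contrast, the 2 highest and 2 lowest log2 fold changes among called genes with a mean log2 CPM of at least 2. For population contrasts it names the 3 highest and 3 lowest, and for the interaction the 15 smallest adjusted p-values. It also names all tested members of the lists of mitochondrially encoded, Y-linked and Stellate genes, with up to 4 members per list by p-value. Of the genes it names, 1 is not reported here. Lists were tested in the 12 haplotype contrasts with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, for the 29 lists with at least 5 tested members, adjusted over 348 tests. Of 98 calls with the preset correlation, 1 held with an estimated correlation, that of the cytochrome P450 genes in Y ZH23. The share of members called in the F tests was compared with that of all genes by Fisher's exact test, 2-sided and adjusted over the 31 lists within each factor. This test takes genes as independent, so that its p-values may be too small for lists whose members vary together.

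The alternatives set in advance were RLE in place of TMM, no filter, no batch term, DESeq2 1.42.0 and limma-voom in place of edgeR, a model without interaction, a replicate block, each batch alone, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the 6 libraries with over 20% of reads aligned to several places and leaving out their 6 partners of the same combinations. Others were the share of such reads as a covariate, 3 surrogate variables from sva 3.50.0, and, for named genes, leaving out each library in turn and a model without interaction. Fits that leave out libraries kept the same 12470 genes, and those that leave out 1 library also kept the dispersion trend of all 72. In these the lone remaining library of a combination is assumed to vary like the other groups. Of the genes tested, 157 had 0 counts in both libraries of a combination. The fold change of such a gene depends on the prior count, and its contrast has no power where a combination at 0 lies on the higher side. Of 53 named values 8 belong to such genes, namely Osi22, Pp1-Y1 and CG31326. Labels were shuffled 40 times within strata for each count; this number, lower than planned for reasons of computing time, was settled before the shuffled counts were seen.

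The model was tested on simulated data with the dispersion trend of these libraries, without batch or replicate effects, and with 20 genes changed per fold. For haplogroup and Y effects it called 10 of 20 genes at 1.5-fold and 20 of 20 at 2-fold, with 4 and 9 calls outside the changed genes. For the interaction it called 19 of 20 genes at 2-fold and 20 of 20 at 4-fold with 0 calls outside. In the interaction simulation DESeq2 made 77 calls outside the changed genes and limma-voom 46, so that the DESeq2 interaction calls are given beside those of edgeR and not in their place.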

Results

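The crosses address how the mitochondrial haplogroup and the Y haplotype, alone and together, shape the transcriptome of the whole male. Expression of 517 of 12470 genes differed between Y haplotypes and that of 254 between mitochondrial haplogroups, while 0 genes passed the edgeR test of the interaction (239 at an unadjusted p under 0.05, 0 by limma-voom and 15 by DESeq2). Which factor had more genes depended on the model, since without a batch term 601 genes were called for the haplogroup and 362 for the Y. Leaving out the 6 partners of libraries with over 20% of reads aligned to several places gave 3769 and 2819. The Y haplotype calls took in genes of the eye, the gut, the cuticle and the cytochrome P450 family, and the mitochondrial calls took in antimicrobial peptides and digestive proteases. For the median gene the Y haplotype held 8.99% of the variance and the haplogroup 7.38%, where 7.04% would fall to each by its degrees of freedom. Shares were taken in the order batch, haplogroup, Y haplotype and interaction, so that variance common to batch and haplogroup was counted as batch. The interaction held 25.2%, where 35.2% would fall to it by its degrees of freedom. Differences between the 2 libraries of a combination held 45.0%, where 49.3% would. Batch, a term of the model, held 6.13% and reached 3648 genes.

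A transcript on the X chromosome separated the mitochondrial haplogroups more sharply than any other feature by adjusted p. The noncoding RNA asRNA:CR44894 (X, 10114340 to 10208574) averaged 38.1 CPM ± 18.8 in B38, 31.8 ± 7.93 in N01 and 30.4 ± 11.4 in N02 (SD, n = 12 each), against 0.425 in B39, 3.54 in I02 and 2.97 ± 8.33 in N23, with an adjusted p of 4.12e-15 in the F test. In N23 mtN23_YN03 replicate 2 had 29.4 CPM and the other libraries at most 1.73. Whether that library carries a wrong or mixed haplogroup label was not tested. Its log2 fold change against the other haplogroups was 3.53 ± 0.28 in B38 (adjusted p = 1.46e-11), 2.87 ± 0.27 in N01 (2.79e-09), 2.71 ± 0.28 in N02 (6.27e-08) and -3.65 ± 0.55 in N23 (0.000566). B39, which had the lowest mean of this RNA, was not called lower, as all 8 genes called for B39 were higher. This transcript is annotated antisense to other genes, and its level is uncertain where reads overlap both. Sons take the X from the same mother as the mitochondria. An effect of the haplogroup on this RNA therefore cannot be told apart from a difference between the X chromosomes of the maternal lines. Osi22 (3R, 13290629 to 13291846), of the Osiris family of insect membrane proteins, rose in N01 by a log2 fold change of 7.18 ± 0.66 (adjusted p = 1.69e-07). Osi22 averaged 19.4 CPM ± 19.1 in N01 and 3.89 in N02, and under 0.3 CPM in the other haplogroups. Of 12 N01 libraries 5 lay above all other libraries, which reached 19.3 CPM, while the lowest N01 library had 0 CPM. That 10 of 12 lay above the median of all other libraries says little, as most of those had few or no reads of this gene. N01 had 5 genes called, all higher. These include Hsp83, the cytosolic Hsp90 chaperone, with a log2 fold change of 0.61 ± 0.10 (adjusted p = 0.000713), and mt:ND3, a subunit of respiratory complex I encoded in the mitochondrial genome, with 1.49 ± 0.29 (0.0145). Heat shock proteins were higher as a list in N01 by camera (adjusted p = 0.000896, and adjusted p = 0.173 with an estimated correlation), although Hsp83 was the 1 member of 8 that passed. The N01 count fell to 3 without mtN01_YB11, mtN01_YN03 or mtN01_YN07 replicate 1 or without mtN01_YZH23 replicate 2, and in batch 1 alone neither Osi22 in N01 nor asRNA:CR44894 in N23 was called (adjusted p = 1 and 0.146, with lowest values over 6 alternatives of 1.25e-09 and 1.83e-10). In batch 1 alone Hsp83 (0.606) and mt:ND3 were not called either. Osi22 had 0 counts in 15 of 36 combinations, and was not called without mtN01_YB11 replicate 1 or mtN01_YZH23 replicate 2, each of which left a combination of N01 at 0 (adjusted p = 1). In a model without interaction its log2 fold change was 6.14 ± 0.47 (5.45e-16). The call of asRNA:CR44894 in N23 ended without any of 7 single libraries (adjusted p up to 1, without mtB39_YB04 replicate 1 or mtI02_YB11 replicate 2), and in a model without interaction it was -2.35 ± 0.46 (0.00563).

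**Figure D1:**
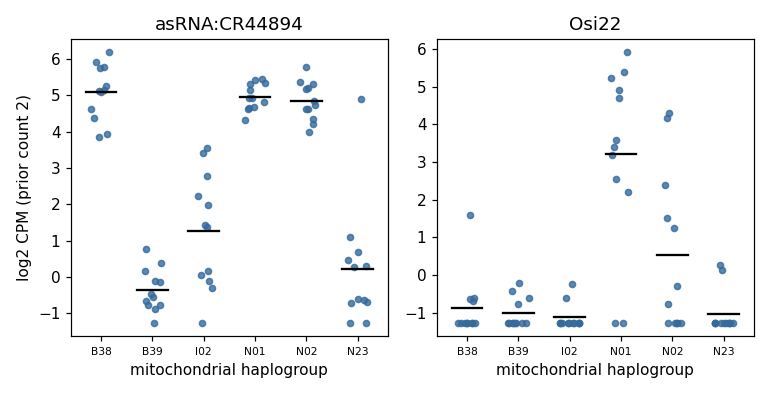
Expression of asRNA:CR44894 and Osi22 in each of the 72 libraries, as log2 CPM on the vertical axis, by mitochondrial haplogroup on the horizontal axis; points are libraries (12 per haplogroup) and the line is the mean. The antisense transcript is high in B38, N01 and N02, and Osi22 reaches its highest levels in N01.

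Males with the B38 mitochondria, from Beijing, showed more of the immune transcripts edin, CecC and AttD and of the chitinase gene Cht4, and less of the seminal fluid genes Acp36DE and Acp33A. These are among the 40 genes called for B38 both in all libraries and without the 6 libraries in which over 20% of reads aligned to several places. The log2 fold change of edin, an immune-induced gene, was 2.29 ± 0.48 in all libraries and 2.66 ± 0.54 without the 6, that of CecC, which encodes a cecropin, 1.57 ± 0.43 and 1.76 ± 0.43, and that of AttD, which encodes an attacin, 1.63 ± 0.35 and 1.73 ± 0.38. Cht4 rose by 0.98 ± 0.21 and 1.25 ± 0.22, MtnD, a metallothionein that binds metal ions, by 0.84 ± 0.10 and 0.69 ± 0.11, and Socs36E, an inhibitor of JAK/STAT signalling, by 0.52 ± 0.12 and 0.65 ± 0.11. Acp36DE, needed for sperm storage in the mated female, had log2 fold changes of -0.31 ± 0.10 and -0.47 ± 0.11, and Acp33A of -0.43 ± 0.08 and -0.39 ± 0.09. The adjusted p-values without the 6 libraries were 0.0166 for edin, 0.0477 for CecC, 0.0299 for AttD, 0.00569 for Cht4, 0.00263 for MtnD, 0.0047 for Socs36E, 0.0477 for Acp36DE and 0.0454 for Acp33A. The genes of this paragraph were picked from the 40 after their values were seen.

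In all libraries 1213 genes were called for B38, 854 higher and 359 lower, and without the 6 libraries 56 were, 32 higher and 24 lower. Of the 6 libraries 4 carry B38: 33.6% of reads aligned to several places in mtB38_YB04 replicate 1 (95% Wilson interval 33.55% to 33.61%), and 35.5% in mtB38_YB11 replicate 1 (35.45% to 35.52%). The share was 28.7% in mtB38_YN03 replicate 1 (28.67% to 28.74%) and 24.9% in mtB38_YN07 replicate 1 (24.90% to 24.96%). The median over all libraries was 12.3%. The other libraries of the 6 are mtI02_YN03 replicate 1 at 29.2% (29.14% to 29.21%) and mtN23_YB04 replicate 1 at 20.2%. Just under the limit lay mtI02_YZH23 replicate 1 at 19.9%, so that the limit of 20% does not fall in a gap between libraries. The B38 count was 146 without mtB38_YB11 replicate 1 and 2477 without mtB38_YB11 replicate 2, and 9 libraries moved it by more than 1.5 times. Among the genes that the rule names, the detoxification gene Cyp6a2 (2R, 6779749 to 6781491) had a log2 fold change of 3.28 ± 0.38 in B38 (adjusted p = 6.48e-07), and 2.25 without the 6 libraries (adjusted p = 0.0792, the highest of 6 alternatives, the lowest being 9.31e-12). CG10761 and the glycosyltransferase gene Ugt37A2 were lower, by -1.25 ± 0.26 (adjusted p = 0.00308) and -1.17 ± 0.33 (0.0205), and were also not called without the 6 libraries (0.193 and 0.182, the highest of 6 alternatives for each, the lowest being 0.000165 and 0.00293). Ugt37A2 was also not called without mtB38_YB04, mtB38_YB11 or mtB38_YN03 replicate 1 or without mtB38_YZW139 replicate 2 (0.0533, 0.0685, 0.0638 and 0.0561). Seminal fluid proteins fell as a list in B38 (camera adjusted p = 2.66e-11, and adjusted p = 0.0514 with an estimated correlation), with 19 of 61 members lower and 0 higher, among them Acp54A1 at -0.68 and Sfp70A4 at -0.49. Without the 6 libraries 3 members fell, which do not include Acp54A1 and Sfp70A4 (adjusted p = 0.261 and 0.265), and the camera adjusted p was 1.64e-10. Antimicrobial peptides had 7 of 32 members higher and 1 lower (camera adjusted p = 0.0132, and 0.8 with an estimated correlation), and 3 members higher without the 6. Neuronal genes rose as a list, with 8 of 18 members higher (camera adjusted p = 2.22e-05, and 0.502 with an estimated correlation), but not without the 6 libraries (0.626). Cytosolic ribosomal proteins fell, with 5 of 90 members called (camera adjusted p = 0.000807, and 0.751 with an estimated correlation), and missed the threshold without the 6 (0.0532).

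**Figure D2:**
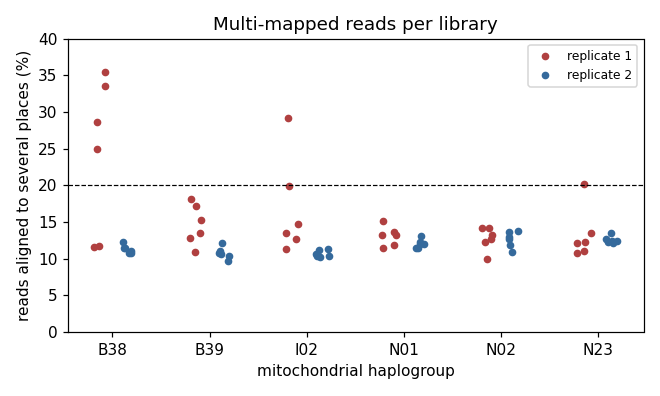
Percent of reads that aligned to several places in each of the 72 libraries, by mitochondrial haplogroup on the horizontal axis; points are libraries, marked by replicate, and the dashed line is at 20%. The 6 libraries above the line are all of replicate 1, and 4 of them carry B38.

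The remaining mitochondrial haplogroups differed from their peers in fewer genes, immune and digestive genes among them. Males with N23 had lower transcripts of Jonah serine proteases, which digest protein in the midgut. Jon25Bi averaged 530 CPM ± 234 in N23 against 1786 ± 712 in B38 (SD, n = 12). Its log2 fold change was -1.27 ± 0.21 (adjusted p = 0.00124), and all 12 N23 libraries lay under the median of the others. Jon66Ci at -1.42 ± 0.32 (adjusted p = 0.0443), Jon65Ai at -1.10, Jon25Bii at -1.14 and Jon25Biii at -0.78 fell with it, while CG15365 and CG10761 rose by 1.16 ± 0.22 (0.00818) and 0.99 ± 0.22 (0.0365). Digestive enzymes fell as a list in N23 (5 of 46 members, camera adjusted p = 6.7e-11, and adjusted p = 0.22 with an estimated correlation). In I02 the same list rose (5 members, camera adjusted p = 4.94e-06, and adjusted p = 0.379 with an estimated correlation), with Jon66Ci at 1.22 ± 0.26 (adjusted p = 0.017) and the maltases Mal-A4 and Mal-B2 at 0.60 each. I02 males also had more of Def, which encodes defensin (1.62 ± 0.35, adjusted p = 0.0208), and less of ninaE, which encodes the main rhodopsin of the eye (-0.70 ± 0.17, 0.0405), and of the neuropeptide-like gene Nplp3 (-0.88 ± 0.21, 0.0396). Tom40, the channel through which proteins enter mitochondria, fell in I02 by 0.40 on the log2 scale (SE 0.08, adjusted p = 0.00693). Without the 6 libraries Jon66Ci in N23 (adjusted p = 0.239) and CG10761 (0.686) were not called, nor were Def (0.106), Jon66Ci (0.0614), ninaE (0.0702) and Nplp3 (0.165) in I02. Over 6 alternatives the adjusted p ranged from 0.000463 to 1 for Jon66Ci and from 0.00822 to 1 for CG10761 in N23, and in I02 from 0.00209 to 0.207 for these genes. B39 had 8 genes called, all higher, with Mtkl, related to the antimicrobial peptide metchnikowin, at 1.88 ± 0.33 (0.0157) and p-cup (X, 17446350 to 17448774), a gene of late spermatogenesis, at 1.22 ± 0.25 (0.0332). In batch 1 alone p-cup (0.191) and CG15365 (0.58) were not called, with lowest values over the alternatives of 0.0068 and 0.000742. N02 had 3, with CG14621 at -0.82 ± 0.16 (0.0431) beside asRNA:CR44894. Calls that ended without single libraries were those of Mtkl for 5 libraries (adjusted p up to 0.3, without mtB39_YZH23 replicate 2), p-cup for 16 (0.544, mtB39_YB11 replicate 1), CG14621 for 32 (0.79, mtN02_YN03 replicate 1) and CG15365 for 5 (0.183, mtN23_YB04 replicate 2). In N23 those of CG10761 ended for 20 (0.634, mtN23_YZH23 replicate 1) and Jon66Ci for 49 (0.304, mtN23_YB11 replicate 1). In I02 they ended for 3 libraries for Jon66Ci (0.123, mtI02_YB04 replicate 2), 4 for Def (0.137, mtI02_YN03 replicate 1), and 16 for Nplp3 and 26 for ninaE (0.14 each, mtI02_YN07 replicate 2). The counts were 50 for I02, 42 higher and 8 lower, and 18 for N23, 6 higher and 12 lower.

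Leaving out 1 library moved several of these counts. The I02 count was 19 without mtI02_YB04 replicate 2 and 212 without mtI02_YN03 replicate 2, with 16 libraries moving it by more than 1.5 times, and the N23 count 5 without mtN23_YB11 replicate 1 and 25 without mtB38_YZW139 replicate 1, with 14 moving it so. B39 had 0 genes called without mtB39_YZW139 replicate 1 or without mtB39_YN03, mtB39_YN07 or mtB39_YZH23 replicate 2, and 15 without mtB39_YN07 replicate 1, with 17 moving it. N02 had 1 without mtB38_YB04 replicate 1, with 28 moving it. For the F test of the haplogroups, the 254 genes became 106 without the 6 libraries with many reads aligned to several places, of which 80 were shared, 108 without mtB38_YB11 replicate 1 and 764 without mtB38_YB11 replicate 2, with 12 libraries moving it. Over haplogroups, 8 of 32 antimicrobial peptide genes were called, 17 adjusted over the list alone. This was more than expected from all genes if genes are taken as independent (Fisher's exact test, adjusted p = 5.67e-06). Of digestive enzymes 7 of 46 were called and 10 adjusted over the list alone (adjusted p = 0.000564), and of photoreceptor genes 4 of 22 and 7 adjusted over the list alone (0.00952). Without the 6 libraries the calls were 3, 7 and 0. As a list, antimicrobial peptides fell in N02 with 0 members called (camera adjusted p = 4.23e-16, and adjusted p = 0.22 with an estimated correlation). They rose in I02 with 2 members called (6.19e-07, and adjusted p = 0.482 with an estimated correlation) and in B39 with 1 (3.14e-06, and adjusted p = 0.538 with an estimated correlation). The reference of N02 includes these haplogroups, so that its fall is not independent of their rise. Photoreceptor genes rose in B39 with 0 of 22 members called (camera adjusted p = 1.22e-08, and adjusted p = 0.301 with an estimated correlation).

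The 3 genes that the rule names as highest with mitochondria from Beijing against those from the Netherlands belong to the humoral immune response. Lists were not tested in this contrast. The log2 fold change was 3.13 ± 0.53 for edin (adjusted p = 0.00135), 3.09 ± 0.57 for DptA, which encodes a diptericin against Gram-negative bacteria (0.00364), and 2.81 ± 0.60 for IBIN, an infection-induced gene (0.0246). Mean CPM of edin was 77.4 ± 105 in B38 and 39.7 in B39, against 6.44 in N01, 5.69 in N02 and 3.61 in N23, and that of DptA 147 and 112 against 32.2, 14.4 and 12.2 (n = 12 each). I02, from Ithaca and outside this contrast, averaged 44.2 CPM of edin and 76.2 of DptA. Lower with Beijing mitochondria were CG42329 at -0.87 (0.0246), CG3348 at -0.86 (0.0401) and the chemosensory gene CheB38b at -0.58 (0.026), of which CG3348 (0.076) and CheB38b (0.074) were not called without the 6 libraries. In batch 1 alone none of the lower genes was called (0.154, 0.158 and 0.179 in that order, the highest over 6 alternatives, with lowest values from 0.00153 to 0.0051). The contrast called 38 genes, 27 higher and 11 lower, 12 without mtN01_YN07 replicate 1 and 89 without mtB38_YZW139 replicate 1, and 21 libraries moved the count by more than 1.5 times. Batch 2 holds only second replicates of N01, N02 and N23, so that this contrast is partly tied to batch and replicate number. With a replicate block it called 1830 genes, 36 of the 38 among them. Single libraries ended the calls of IBIN for 9 (adjusted p up to 1, without mtB39_YZH23 replicate 2), CG42329 for 6 (0.0783, mtN01_YN07 replicate 1), CG3348 for 30 (0.131, mtN02_YZH23 replicate 1) and CheB38b for 8 (0.0721, mtN02_YN07 replicate 1), and of edin and DptA for 0. The SD of edin in B38 exceeds its mean, so that a few libraries carry much of that level.

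Of 36 tested features of the mitochondrial genome 1 was called between haplogroups, and 2 without the 6 libraries with many reads aligned to several places. The fixed list holds 15 of them, without transfer RNAs, of which mt:ND3 was called (adjusted p = 0.00154), 4 were when adjusted over the list alone, and the others had adjusted p-values from 0.0739 to 0.916. Mean mt:ND3 was 17.8 CPM ± 11.9 in N01, 12.35 ± 10.87 in N23 and 12.0 ± 9.53 in B38 (SD, n = 12 each). It was 6.11 in B39, 4.13 in I02 and 3.69 ± 1.27 in N02. All 12 N01 libraries lay above the median of the others, but only 2 lay above all others. In B38, mt:CoII, a core subunit of cytochrome c oxidase, had a log2 fold change of -0.45 (adjusted p = 0.0429), and mt:ATPase6, a subunit of ATP synthase, -0.51 (0.037), and without the 6 libraries neither was called (0.363 and 0.369). Between Y haplotypes the large ribosomal RNA mt:lrRNA differed (adjusted p = 0.0409). It averaged 1447 CPM ± 1570 in B04 and 1513 ± 1156 in B11 against 4505 ± 5554 in N03, 3510 ± 2918 in N07, 2779 ± 2895 in ZH23 and 3536 ± 3299 in ZW139 (SD, n = 12 each). It was the 1 mitochondrial gene called for the Y, also when adjusted over the list alone, and without the 6 libraries 0 of 15 were called for the Y. A ribosomal RNA is read by this assay only where it is polyadenylated or primed internally, and nuclear copies of mitochondrial sequence are known in flies, so that these levels are uncertain. By camera the list rose in N01 (adjusted p = 0.000183, and adjusted p = 0.587 with an estimated correlation) and in Y N07 (4.79e-05, and 0.587), and fell in Y B04 (0.00027, and 0.587).

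Nuclear genes for mitochondrial functions had few or no calls in the F tests of either factor, but their shares did not differ from that of all genes. By Fisher's exact test the adjusted p was 0.242 or more for the lists of this paragraph. It was 0.743 for the haplogroup and 0.295 for the Y in nuclear OXPHOS subunits. The counts therefore do not show that these genes were spared. For haplogroup and for Y haplotype, 0 of 72 nuclear OXPHOS subunits, 0 of 26 testis paralogs of such subunits, 0 of 71 mitochondrial ribosomal proteins and 0 of 13 TCA cycle enzymes were called by edgeR, and the count was also 0 adjusted over the list alone. The same held for 90 cytosolic ribosomal proteins and 15 heterochromatin and piRNA factors. Of 17 genes of mitochondrial import, 1 was called for the haplogroup and 0 for the Y, and of 18 genes of mitochondrial stress and mtDNA maintenance, 0 and 1. Glycolysis had 1 and 0 of 13 genes called, dosage compensation 1 and 0 of 7, proteasome subunits 0 and 1 of 46, and spermatogenesis genes 0 and 1 of 54. Adjusted over the list alone these counts were the same, except that proteasome subunits had 0 for both factors. In the B38 contrast 3 of 72 nuclear OXPHOS subunits were called, 4 of 71 mitochondrial ribosomal proteins, 3 of 13 TCA cycle enzymes, 2 of 17 import genes and 1 of 18 genes of mitochondrial stress and mtDNA maintenance. Among them were ND-AGGG at a log2 fold change of 1.17, mRpL30 at -0.42, Pdhb at -0.27, Tim8 at 0.54 and Pink1 at -0.32. In B38 0 members of these lists were called by edgeR without the 6 libraries with many reads aligned to several places. The list of testis paralogs holds ND-MNLL, which may not be specific to the testis, and the spermatogenesis list holds Mst57D genes of the accessory gland.

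Pp1-Y1 (Y, 9833 to 10786), a protein phosphatase gene of the Y chromosome, had almost no reads in males with the B04 Y. Counts alone do not tell whether this gene was silent there or its reads were missed. It averaged 0.129 CPM ± 0.184 in B04, against 5.22 in B11, 5.39 in N03, 5.97 in N07, 5.94 in ZH23 and 8.16 ± 2.18 in ZW139 (SD, n = 12 each). Its log2 fold change was -5.53 ± 0.47 in B04 (adjusted p = 1.06e-10), where 11 of 12 libraries lay below every library of the other haplotypes, and 1.62 ± 0.23 in ZW139 (9.01e-05). The B11 and ZH23 contrasts gave 0.88 (0.0476) and 1.08 (0.0128). The reference of these contrasts and of that of ZW139 includes B04 with almost no reads, so that their fold changes exceed the differences among the other haplotypes. A pseudogene of the Mst77Y cluster, Mst77Y-16Psi, was also lower in B04, by -6.16 ± 0.53 (3.46e-10), and higher in N03, N07, ZH23 and ZW139 by 1.43, 1.52, 1.40 and 1.45, in contrasts whose reference includes B04. It is a member of a family of near-identical copies, so its level is uncertain. The list of Y-linked genes also holds CG41561, which the annotation used here does not place on the Y. That gene and the other tested members kl-2, kl-3, kl-5, ORY, ARY, PRY, CCY and Pp1-Y2 had adjusted p-values from 0.0793 to 0.851 for the Y haplotype. Of the list 3 of 10 were called when adjusted over the list alone. For the haplogroup 0 of 10 were, over all genes and adjusted over the list alone. Stellate genes, multicopy genes of the X that the Y is known to repress in the testis, were too weakly counted to test: 0 of 14 annotated members passed the filter on low counts. Y-linked genes rose as a list in ZW139 (camera adjusted p = 0.0077, and adjusted p = 0.301 with an estimated correlation), with Pp1-Y1 the 1 member called. The B04 contrast called 7 genes, among them CG44044 at 0.85 ± 0.14 (0.000706), CG32655 at 0.33 ± 0.07 (0.03) and the small nucleolar RNA host gene Uhg2 at -0.86 ± 0.17 (0.0285). Without the 6 libraries CG32655 (0.114) and Uhg2 (0.24) were not called, and in batch 1 alone CG32655 and CG44044 (0.189 each) and Pp1-Y1 in ZW139 (0.0606) were not. Over 6 alternatives the lowest adjusted p was 0.00265 for CG32655, 0.000666 for Uhg2, 2.44e-05 for CG44044 and 2.06e-07 for Pp1-Y1 in ZW139. Single libraries ended the calls of CG32655 for 19 (0.223, without mtN01_YB04 replicate 1) and Uhg2 for 7 (0.148, mtN23_YB04 replicate 1), and of Pp1-Y1 and CG44044 for 0. The B04 count was 3 without mtB38_YB04 replicate 1 and 563 without mtN23_YB04 replicate 2, and 17 libraries moved it by more than 1.5 times.

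An autosomal gene marked the N03 haplotype nearly as clearly. Sans (2R, 12936891 to 12940412), the fly counterpart of a human Usher syndrome gene, averaged 9.81 CPM ± 3.58 with the N03 Y against means of 2.66 to 3.16, a log2 fold change of 1.81 ± 0.14 (adjusted p = 9.81e-12), with 9 of 12 libraries above all others. The remaining N03 libraries were mtB38_YN03 and mtI02_YN03 replicate 1 and mtN01_YN03 replicate 2, at 6.76, 3.00 and 5.10 CPM, against at most 6.97 with the other Y haplotypes. The gene dl, which encodes the NF-kappaB factor Dorsal, rose in N03 by 0.65 ± 0.10 (0.000422), but was not called in batch 1 alone (0.179, the highest of 6 alternatives, the lowest being 1.93e-06). In N03 the photoreceptor membrane gene chp fell by 3.28 on the log2 scale (SE 0.64, adjusted p = 0.0196) and Dup99B, a seminal peptide gene, by 4.28 (SE 0.95, 0.0362). Without the 6 libraries neither was called (0.0925 and 0.161, with ranges over 6 alternatives of 7.92e-06 to 0.162 and 6.72e-08 to 0.362). N03 had 19 genes called, 6 higher and 13 lower, 2 without mtB39_YN03 replicate 1 and 254 without mtI02_YN03 replicate 2, with 21 libraries moving it by more than 1.5 times. ZW139 had 21 called, 16 higher and 5 lower, 8 without mtN02_YZW139 replicate 1 and 177 without mtB38_YN03 replicate 2, with 38 moving it so. Its lower genes Agpat4 at -0.49 ± 0.11 (0.0486), an acyltransferase of lipid synthesis, and CG43774 at -0.47 ± 0.11 (0.0486) were not called without the 6 (0.0849 and 0.0628, with ranges over 6 alternatives of 0.00489 to 0.145 and 0.00429 to 0.159). N07 had 2 genes called, Mst77Y-16Psi and eater, a phagocytosis receptor of blood cells, at 0.51 ± 0.09 (0.00663; over 6 alternatives 0.00136 to 1, the highest in batch 1 alone), and 1 without mtB39_YN07 replicate 1, mtB38_YN07 replicate 2 or mtN01_YN07 replicate 2. The call of eater ended without these same libraries (0.156, 0.0568 and 0.0557). Those of Dup99B and chp in N03 ended for 15 and 12 single libraries (up to 0.253 without mtN23_YN03 replicate 1 and 1 without mtB38_YB11 replicate 2), and those of Agpat4 and CG43774 for 43 and 41 (0.217 and 0.199, without mtN02_YZW139 replicate 1), while Sans and dl kept theirs without each library. Photoreceptor genes fell as a list in N07, with 0 of 22 members called (camera adjusted p = 9.04e-16, and adjusted p = 0.173 with an estimated correlation), and in N03, with 1 member called (2.74e-14, and adjusted p = 0.193 with an estimated correlation). The reference of both includes B11 and ZH23, where this list rose, so that these falls are not independent of that rise. Cytosolic ribosomal proteins fell in ZW139 with 0 members called (3.17e-09, and adjusted p = 0.474 with an estimated correlation), and spermatogenesis genes rose with 1 (0.000127, and adjusted p = 0.294 with an estimated correlation).

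**Figure D3:**
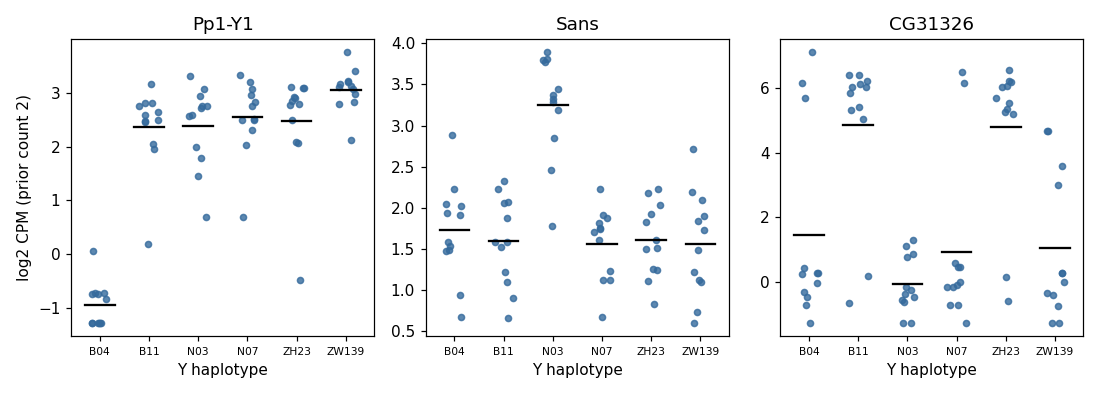
Expression of Pp1-Y1, Sans and CG31326 in each of the 72 libraries, as log2 CPM on the vertical axis, by Y haplotype on the horizontal axis; points are libraries (12 per haplotype) and the line is the mean. Pp1-Y1 is low in B04 and Sans high in N03, while CG31326 is high in most B11 and ZH23 libraries and in some libraries of B04, N07 and ZW139.

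In males with the B11 Y, from Beijing, some genes of vision, digestion and the cytochrome P450 family were higher. As lists they did not pass camera with an estimated correlation. The photoreceptor list rose with 15 of 22 members higher and 0 lower (camera adjusted p = 2.6e-22, and adjusted p = 0.0603 with an estimated correlation). It includes chp at a log2 fold change of 2.90 ± 0.34 (adjusted p = 5.1e-07), ninaA, a chaperone of rhodopsin, at 1.35 ± 0.18 (2.77e-06), and the ultraviolet-sensitive opsin Rh4 at 0.83 ± 0.11 (2.77e-06). Mean Rh4 was 60.8 CPM ± 13.2 in B11 against 28.1 ± 4.94 in N03 (SD, n = 12), and all 12 B11 libraries lay above the median of the others. Digestive enzymes had 9 of 46 members higher (camera adjusted p = 5.3e-05, and adjusted p = 0.491 with an estimated correlation), among them the gut lysozymes LysD at 4.11 ± 0.48 (5.1e-07) and LysP at 1.85, and the maltase Mal-B1 at 1.56 ± 0.21 (4e-06). LysD belongs to a cluster of similar lysozyme genes and may share reads with them. Cytochrome P450 genes had 8 of 76 members higher (1.77e-05, and adjusted p = 0.178 with an estimated correlation), with Cyp6g1, known from insecticide resistance, at 1.15 ± 0.16 (1.14e-05) and a mean of 1592 CPM ± 572. The clock gene Clk rose by 1.08 ± 0.14 (4e-06). The highest called genes were Dup99B (3R, 29715068 to 29715377) at 4.41 ± 0.56 (1.85e-06) and CG31326 at 4.18 ± 0.46 (2.33e-07), and the lowest CG14499 at -1.89 ± 0.46 (0.0141) and CG11854 at -1.30 ± 0.34 (0.0255). Of these 4, the lowest genes were not called in batch 1 alone (0.152 and 0.46, the highest of 6 alternatives for each, the lowest being 0.000122 and 0.00419). CG31326 had 0 counts in 1 combination, and was not called in B11 without mtB38_YB11 or mtI02_YB11 replicate 2 (0.186 and 0.658), nor was CG14499 without these or mtN02_YB11 replicate 2 (0.0559, 0.0811 and 0.0718), nor CG11854 without any of 9 libraries (up to 0.124). In a model without interaction the log2 fold change of CG31326 was 3.10 ± 0.54 (0.000154) and that of Dup99B 3.54 ± 0.76 (0.0026). Seminal fluid proteins rose as a list with 2 of 61 members higher and 1 lower (1.5e-05, and adjusted p = 0.239 with an estimated correlation). The lower member, Acp65Aa at -1.28, is a cuticle protein. Muscle genes fell with 0 of 24 members called (3.73e-05, and adjusted p = 0.322 with an estimated correlation). The B11 contrast called 307 genes, 243 higher and 64 lower, and 493 without the 6 libraries, of which 292 were shared. It called 145 without mtB38_YB11, 76 without mtI02_YB11 and 175 without mtN02_YB11, each replicate 2.

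ZH23, a Y from Zimbabwe, was also marked by P450 genes. P450s had 10 of 76 members higher and 0 lower (camera adjusted p = 8.13e-10, and adjusted p = 0.0473 with an estimated correlation), among them Cyp6a2 at 2.78 ± 0.43 (adjusted p = 0.000102), Cyp6g1 at 0.95 ± 0.17 (0.000598), Cyp6a8 at 1.62 and Cyp12d1-p at 0.60. Mean Cyp6g1 was 1474 CPM ± 585 in ZH23 and 476 ± 135 in N03 (SD, n = 12). Fat body genes had 3 of 11 members higher (2.22e-05, and adjusted p = 0.173 with an estimated correlation), with Lsp1beta, a storage protein, at 1.36 and FASN1, a fatty acid synthase, at 0.53 ± 0.10 (0.00165). Dup99B at 4.14 ± 0.60 (4.73e-05) and CG31326 at 3.83 ± 0.46 (1.94e-06) were the highest genes, and CG7214 at -1.22 ± 0.31 (0.0313) and the cuticle gene Cpr62Bc at -1.12 ± 0.28 (0.0254) the lowest. Digestive enzymes had 7 of 46 members higher and 0 lower, but as a list did not pass (camera adjusted p = 0.451, and 0.911 with an estimated correlation). The trypsin gene zetaTry rose by 3.12 ± 0.57 (0.00128) and chp by 2.43 ± 0.35 (4.73e-05). Photoreceptor genes rose as a list with 2 of 22 members called (4.56e-14, and adjusted p = 0.193 with an estimated correlation). ZH23 had 169 genes called, 145 higher and 24 lower, and 243 without the 6 libraries, of which 158 were shared, although CG7214 was then not called (0.0582, the highest of 6 alternatives, the lowest being 0.00235), and Cpr62Bc was not called in batch 1 alone (0.152, the lowest being 0.00443). CG31326 was not called without mtN01_YZH23 or mtN23_YZH23 replicate 1 (0.96 and 0.385), and CG7214 and Cpr62Bc not without any of 10 and 7 libraries (up to 0.218 and 0.194, without mtN01_YZH23 replicate 1). The count was 28 without mtN01_YZH23, 30 without mtN23_YZH23 and 111 without mtB38_YZH23, each replicate 1, and 68 without mtB39_YZH23, 109 without mtI02_YZH23 and 85 without mtN02_YZH23, each replicate 2.

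The highest genes of B11 and ZH23 varied widely among libraries of the same Y. Mean Dup99B was 6118 CPM ± 3459 in B11 and 5346 ± 2857 in ZH23, against 3039 ± 5751 in B04, 1273 in N07, 1062 in ZW139 and 53.7 ± 78.0 in N03 (SD, n = 12). CG31326 reached 10 CPM in 10 of 12 libraries of B11 and of ZH23, in 3 of B04 and of ZW139, in 2 of N07 and in 0 of N03, a limit chosen after the values were seen. On log2 CPM with a prior count of 2, which narrows differences between low levels, the 2 libraries of a combination differed by more than 8-fold in 9 of 36 combinations for CG31326, 13 for Dup99B, 12 for LysD, 7 for zetaTry and 6 for chp. On this scale 0 combinations did for Sans and 1 for Pp1-Y1, while in plain CPM Pp1-Y1 had 0.305 and 6.74 in mtI02_YZH23 and 0.729 and 8.52 in mtB38_YB11.

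Across all Y haplotypes, 16 of 22 photoreceptor genes were called, 18 adjusted over the list alone (Fisher's exact test, adjusted p = 1.12e-16). Members of a list are measured in the same pools and can vary together, which Fisher's test does not allow for. Its p-values here therefore do not measure the strength of an enrichment. Digestive enzymes had 11 of 46 called and 18 adjusted over the list alone (3.09e-05), P450s 13 of 76 and 18 adjusted over the list alone (0.000132), and cuticle proteins 8 of 44 and 12 adjusted over the list alone (0.00304). Fat body genes had 4 of 11 called and 6 adjusted over the list alone (0.00473), and seminal fluid proteins 7 of 61 and 19 adjusted over the list alone (0.0658). The other lists with a member called for the Y had Fisher adjusted p-values from 0.892 to 1. They were antimicrobial peptides with 2 of 32 genes called and 2 adjusted over the list alone, odorant-binding proteins with 2 of 35 and 2, glutathione S-transferases with 1 of 34 and 9, and UDP-glycosyltransferases with 1 of 24 and 1. Further such lists were muscle genes with 1 of 24 and 4, clock genes with 1 of 10 and 3, and ovary and yolk genes with 1 of 10 and 1. The stress-induced Turandot genes had 0 of 4 called and 3 adjusted over the list alone, and neuronal genes and heat shock proteins 0 by either count. The F test for the Y called 517 genes, 633 without the 6 libraries, of which 443 were shared.

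For the mitochondrial haplogroup, P450s had 5 of 76 genes called and 18 adjusted over the list alone (Fisher's exact test, adjusted p = 0.149), cuticle proteins 3 of 44 and 4 adjusted over the list alone (0.372), and neuronal genes 1 of 18 and 7 adjusted over the list alone (0.64). Seminal fluid proteins had 1 of 61 called and 11 adjusted over the list alone, heat shock proteins 1 of 8 and 3, clock genes 1 of 10 and 3, ovary and yolk genes 1 of 10 and 3, and fat body genes 1 of 11 and 2. Their adjusted p-values ranged from 0.628 to 1. UDP-glycosyltransferases had 0 of 24 called by edgeR and 6 adjusted over the list alone, and odorant-binding proteins 0 of 35 and 1. Glutathione S-transferases, muscle genes and Turandot genes had 0 by either count.

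**Figure D4:**
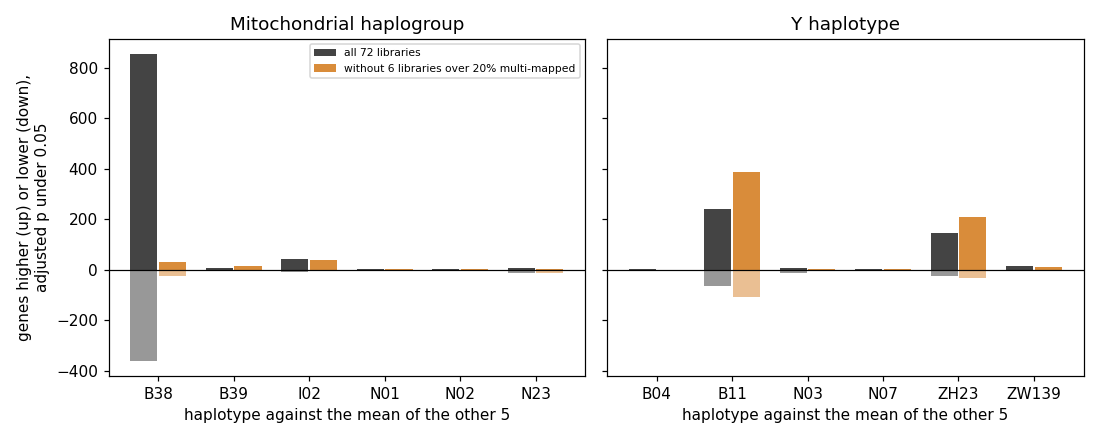
Number of genes called higher and lower in each mitochondrial haplogroup and Y haplotype against the mean of the others, in all 72 libraries and without the 6 libraries in which over 20% of reads aligned to several places. B38 goes from 1213 genes to 56, while Y B11 goes from 307 to 493 and Y ZH23 from 169 to 243.

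By population of origin, Y chromosomes from Beijing differed from those of the Netherlands in 394 genes, 251 higher and 143 lower. Dup99B was higher by a log2 fold change of 3.97 ± 0.71 (adjusted p = 0.00143), LysD by 3.49 ± 0.93 (0.0318) and CG31326 by 3.48 ± 0.85 (0.0181). Pp1-Y1 at -2.76 ± 0.31 (3.67e-07), the troponin C gene TpnC25D at -1.67 ± 0.38 (0.0109) and the serine protease homolog SPH93 at -1.48 ± 0.43 (0.0453) were lower. The Pp1-Y1 value averages a gene with almost no reads in B04 with an expressed one in B11, so that it does not describe both Beijing Y chromosomes. Nor do those of CG31326 and LysD, which reached 10 CPM in 10 of 12 libraries of B11 each but in 3 and 2 of B04, and in 2 each of N07. Dup99B averaged 6118 CPM in B11 and 3039 ± 5751 in B04. Without the 6 libraries 72 genes were called, 71 of them shared, and LysD (0.178), CG31326 (0.196), TpnC25D (0.0681) and SPH93 (0.104) were not. In batch 1 alone these (0.151 to 1) and Dup99B (0.0633) were not called, while the lowest values over 6 alternatives were 2.77e-06 to 0.0108 and 2.4e-08. Single libraries ended the calls of LysD for 13 (up to 0.305, without mtI02_YB11 replicate 2), CG31326 for 6 (1, mtN01_YB04 replicate 2), SPH93 for 36 (0.161, mtB39_YN07 replicate 1) and TpnC25D for 1 (0.0533, mtN02_YN07 replicate 2). The count was 95 without mtN23_YB04 replicate 1 and 1054 without mtN23_YB04 replicate 2, and 25 libraries moved it by more than 1.5 times. The Zimbabwe Y chromosomes differed from the others in 4 genes, 3 higher and 1 lower, among them Pp1-Y1 at 1.69 ± 0.22 (7.84e-06). The reference of this contrast includes B04, where Pp1-Y1 had almost no reads, and ZH23 at 5.94 CPM did not exceed N07 at 5.97. This value therefore does not describe both Zimbabwe Y chromosomes. Without mtI02_YZH23 replicate 2 Pp1-Y1 was not called in this contrast (log2 fold change 1.39, adjusted p = 0.498).

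Combinations of mitochondria and Y had no detectable effect beyond the sum of both by the edgeR test. It called 0 genes for the interaction, with 239 genes at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 15. The DESeq2 genes include CG18180 and Jhbp13 (adjusted p = 0.00278 each), Dup99B (0.032), the maltase Mal-B2 (0.0469) and CG31326 (0.0498), and their adjusted p by edgeR was 1. On simulated data with the dispersion trend of these libraries the edgeR test called 19 of 20 genes with a 2-fold interaction in same-population pairs. The simulation had no batch effect, no shared replicate difference and no libraries with many reads aligned to several places. It therefore cannot tell whether an interaction of that size would have been seen here, and 0 calls do not exclude it. Leaving out mtI02_YN03 replicate 2 gave 34 genes, leaving out mtB39_YZW139 replicate 1 gave 1, and leaving out the 6 partners of the libraries with many reads aligned to several places gave 147. Pairs of mitochondria and Y from the same population, of Beijing and the Netherlands, differed from mixed pairs in 0 genes by edgeR, with 126 at an unadjusted p under 0.05, and in 0 by DESeq2.

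Called genes were unevenly placed on the chromosomes. Of tested X-linked genes 2.84% were called for the haplogroup and 1.71% for the Y haplotype. On the autosomal arms 2L, 2R, 3L and 3R the shares were 2.12%, 1.91%, 1.72% and 1.89% for the haplogroup and 4.98%, 3.42%, 5.24% and 4.76% for the Y haplotype. The X share exceeded the autosomal one for the haplogroup (odds ratio 1.51, Fisher's exact test, 2-sided p = 0.0125) and was below it for the Y haplotype (odds ratio 0.363, p = 3.14e-10). Genes are not independent of each other in these tests.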

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

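Chosen only after the result was seen were the fits without the 6 libraries or their partners and with the share of reads aligned to several places as a covariate, the tests of wrong Y labels and of the lowest library, and the tests of the X against the autosomes for either factor.

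The share of reads aligned to several places, a count outside the measured genes, reached 35.5% in mtB38_YB11 replicate 1 (95% Wilson interval 35.45% to 35.52%), and all 6 libraries above 20% are of replicate 1, 4 of them with B38. Without these 6 libraries B38 had 56 genes called in place of 1213, and without the 6 partners 5115. The fit without the partners leaves 4 combinations of B38 with only their library above 20%, which can itself raise the count. It therefore cannot tell how much of the drop to 56 comes from having fewer libraries. With the share as a covariate, which kept all 72 libraries, the count was 324. Most of the B38 count may therefore follow from how these libraries differ, whether in RNA, flies or preparation, which the files cannot separate. For the 40 genes called both with and without the 6 libraries, such as edin, MtnD and Acp36DE, an effect of the B38 mitochondria stays open as a hypothesis, as does that of anything else that came with the B38 mothers. Shuffled labels called at most 333 genes.

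The highest genes of Y B11 and Y ZH23, among them Dup99B, CG31326 and LysD, were high in most but not all libraries of these haplotypes. With the share of reads aligned to several places as a covariate, 480 genes were called for B11, against 307, and 228 for ZH23, against 169. A linear trend with that share therefore does not account for the number of genes called. These counts do not show whether the levels of Dup99B, CG31326 and LysD in single libraries vary with it. In 69.6% of 56 pairs of gene and haplotype with a log2 fold change of at least 2, 28 for each haplotype, the lowest library lay below the median of the other haplotypes. This share takes the lowest of 12 libraries for genes picked by their fold change, so that for these genes as a set an effect of the Y haplotype alone stays open. For CG31326 and Dup99B the Y was not all that set the level: replicates 1 and 2 of mtN23_YB04 both had 0 CPM of Pp1-Y1, as B04 has, but 138 and 0.788 CPM of CG31326 and 14300 and 114 of Dup99B. For Pp1-Y1, the gene that marks B04, 1 of 24 libraries of B11 and ZH23 lay at or below the highest B04 library, namely mtI02_YZH23 replicate 1 at 0.305 CPM, and it had 95.0 CPM of CG31326. Of 4 libraries of B11 and ZH23 with CG31326 under 10 CPM, mtB38_YB11 replicate 1 had 0.729 CPM of Pp1-Y1, mtI02_YB11 replicate 1 5.59, and mtN01_YZH23 and mtN23_YZH23 replicate 2 5.24 and 8.21. The 3 libraries of B04 with CG31326 over 10 CPM had at most 0.149 CPM of Pp1-Y1. Libraries with a wrong Y label cannot be told apart by this gene unless they come from B04, so that wrong or mixed labels stay open. They stay open too for 3 libraries of N03, mtB38_YN03 and mtI02_YN03 replicate 1 and mtN01_YN03 replicate 2, whose Sans level lay among those of the other haplotypes. Reads aligned to several places were 28.7%, 29.2% and 11.4% in these, in that order, against a median of 12.3% over all libraries. The share was 35.5% in mtB38_YB11 replicate 1 and 19.9% in mtI02_YZH23 replicate 1, where Pp1-Y1 was low. Whether a high share goes with altered levels of Sans or Pp1-Y1 was not tested. An influence of the mitochondria, of the state of the flies in a vial or of their food may also vary the highest genes of B11 and ZH23 between pools, and was not tested.

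Genes on the X were called more often for the haplogroup (Fisher's exact test, p = 0.0125) and less often for the Y (p = 3.14e-10) than autosomal genes. The places of the fixed lists do not account for the latter, as it held with list members left out (Fisher's exact test, p = 2.73e-08). The design offers an explanation for both, since sons take the X from the mitochondrial line and a set of autosomes from the Y line: remnants of other nuclear genomes in the maternal or paternal lines may add to the calls of either factor. For the haplogroup the odds ratio was 1.62 without the 6 libraries (Fisher's exact test, p = 0.0519), so that an effect of those libraries cannot be told apart with 23 calls on the X. A biological effect of mitochondria or Y on X-linked genes stays open as untested.

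Other ways of assigning labels were tried for every count, by shuffling haplotypes within the other factor and batch, each time with 41 assignments, the real one included. Where only the real assignment gave a count as large, the share was 1 of 41, the lowest that 41 assignments can give. Taken by itself, such a count lay beyond all shuffled ones, which argues against chance but does not exclude it. The shuffles did not keep the replicate number, although replicates of B38, B39 and I02 differed in a shared way. The shares were not adjusted over the 19 counts. A share of 1 of 41 held for the haplogroup F test, with 254 genes against 1 in the highest other assignment. So it did for B38 with 1213 against 333 and N01 with 5 against 1. It held for N02 with 3 against 1, N23 with 18 against 0 and the mitochondrial Beijing contrast with 38 against 1. It also held for the Y F test with 517 against 13, Y B04 with 7 against 1, B11 with 307 against 92, N03 with 19 against 1, ZH23 with 169 against 2, the Y Beijing contrast with 394 against 327 and Zimbabwe with 4 against 0. For 3 of these the margin rests on few libraries, as their counts without some libraries lie below the highest other assignment. B38 had 146 without mtB38_YB11 replicate 1 and 56 without the 6 libraries, B11 had 76 without mtI02_YB11 replicate 2, and the Y Beijing contrast had 95 without mtN23_YB04 replicate 1 and 72 without the 6. N02 had 1 without mtB38_YB04 replicate 1, as many as the highest other assignment. In B39 (8 against 27), I02 (50 against 416) and Y ZW139 (21 against 34) 2 of 41 assignments gave as many, a share of under 0.05. In Y N07 4 of 41 did, with 2 genes against 65, and chance cannot be excluded. For the interaction and the same-population contrast, both with 0 genes, all 41 gave as many, with up to 973 and 1027. Assignments that call several times the real count, as in B39, I02, Y N07, the interaction and the same-population contrast, point to a structure among the samples that haplotypes and batch do not describe.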

How the results depend on the processing

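Alternatives chosen only after the result was seen were the fits without the 6 libraries with over 20% of reads aligned to several places, without their 6 partners, with the share of such reads as a covariate, with 3 surrogate variables, and the named genes without each library in turn and without interaction. All others were planned. RLE size factors moved 0 counts by more than 1.5 times, and limma-voom, which was run for the 3 F tests, moved 0 of these. The interaction stayed at 0 by edgeR in all alternatives but that without the 6 partners and the leaving out of single libraries, and the same-population contrast stayed at 0 in every alternative run. What moved the counts was not tested, apart from B38 and the Y contrasts B11 and ZH23, as given among the results for a closer look. Depth limits weakly expressed genes: of 17324 features 12470 had enough counts to be tested.

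Counts of genes called that moved by more than 1.5 times are given in the order haplogroup F test, Y F test, interaction, then single contrasts. With DESeq2 they were 652 for the haplogroup, 875 for the Y and 15 for the interaction. For single contrasts they were 21 for B39, 105 for I02, 13 for N02, 34 for N23, 127 for Y B04, 103 for Y N03, 101 for Y ZW139, 108 for mitochondria of Beijing against the Netherlands and 686 for Y chromosomes of Beijing against the Netherlands. The labels do not say what a replicate number marks. Deviations of replicate 1 correlated by 0.2 on average between combinations of B38, B39 and I02, and by over 0.1 in 99 of 153 pairs, the lowest being -0.405. Replicate 1 was higher on the second principal component in 18 of 18 of these combinations, so that their replicates differ in a shared way that the batch term does not hold. In N01, N02 and N23 the replicate number coincides with batch, and this check says nothing. With a replicate block more genes were called for the haplogroup than for the Y, the reverse of the order without it. The counts were 1639 for the haplogroup, 929 for the Y, 3265 for B38, 86 for I02, 8 for N01, 42 for N02, and 34 for N23. For the Y they were 14 for B04, 77 for Y N03, 368 for Y ZW139, 1830 for the mitochondrial Beijing contrast, 749 for the Y Beijing contrast and 7 for Zimbabwe. In batch 1 alone they were 26 for the haplogroup, 98 for the Y, 296 for B38, 1 for B39, 25 for I02, 1 for N01, and 0 for N23. For the Y they were 2 for Y B04, 40 for Y B11, 2 for Y N03, 0 for Y N07, 76 for Y ZH23, 2 for Y ZW139, 24 for the mitochondrial Beijing contrast, 8 for the Y Beijing contrast and 2 for Zimbabwe. In batch 2 alone, with N01, N02 and N23 only and no interaction, 3 genes were called for the haplogroup and 65 for the Y.

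Without the 6 libraries the counts were 106 for the haplogroup, 56 for B38, 19 for B39, 3 for Y B04, 493 for Y B11, 2 for Y N03, 13 for Y ZW139 and 72 for the Y Beijing contrast. Without their 6 partners they were 3769 for the haplogroup, 2819 for the Y, 147 for the interaction, 5115 for B38, 57 for B39, 498 for I02, and 14 for N01. For the Y they were 1463 for Y B04, 161 for Y B11, 217 for Y N03, 540 for Y ZH23, 1858 for Y ZW139, 1880 for the mitochondrial Beijing contrast, 1150 for the Y Beijing contrast and 2276 for Zimbabwe. With the share of reads aligned to several places as a covariate they were 807 for the Y, 324 for B38, 20 for B39, 130 for I02, 14 for N01, 5 for N02, 480 for Y B11, 31 for Y N03, 66 for the mitochondrial Beijing contrast and 683 for the Y Beijing contrast. With 3 surrogate variables the haplogroup had 851 and the Y 1339. Without a batch term the haplogroup had 601, and in a model without interaction 620. Without a filter on low counts B39 had 14 and Y ZW139 13. Of 98 camera calls 1 held with an estimated correlation, and with the replicate block, in batch 1 alone and without the 6 libraries there were 85, 92 and 94 calls.

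Leaving out 1 library gave 108 to 764 genes for the haplogroup, 381 to 755 for the Y, 0 to 34 for the interaction, and 146 to 2477 for B38. It gave 0 to 15 for B39, 19 to 212 for I02, 3 to 7 for N01, 1 to 4 for N02 and 5 to 25 for N23. For the Y it gave 3 to 563 for B04, 76 to 397 for B11, 2 to 254 for N03, 1 to 3 for N07, 28 to 233 for ZH23 and 8 to 177 for ZW139. The mitochondrial Beijing contrast ranged from 12 to 89, the Y Beijing contrast from 95 to 1054, Zimbabwe from 3 to 6, and same-population pairs from 0 to 0. Ends of a range that lie more than 1.5 times from the full count are given with their library in the account of the results. Camera was not run without each library.

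Of 53 values named by the rule, 53 kept their call with DESeq2 and with RLE, 52 with the replicate block, 50 without a filter, 43 in a model without interaction, 31 without the 6 libraries and 22 in batch 1 alone. Without each library in turn 18 of the 53 kept their call throughout, and 0 changed sign. Those lost without interaction were Nplp3 (0.0606), ninaE (0.0753), CG14621 (0.132), Jon66Ci in N23 (0.236), Uhg2 (0.0626), CG14499 (0.0578), Dup99B in N03 (0.058), eater (0.0688), CG7214 (0.0526) and CheB38b (0.0715). Of the other 140 values of list members, 36 kept their call without each library in turn, 53 in batch 1 alone and 69 without the 6 libraries. Of these 140 values 6 changed sign without the 6 libraries, all in B38: ND-AGGG from 1.17 to -0.43, Prosbeta2 from 0.46 to -0.036, whip from 0.52 to -0.09, Jon99Cii from 0.95 to -0.22, rdgA from 0.46 to -0.092 and TwdlY from 1.58 to -1.02. The cause was not tested.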

Other observations

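The values given here without the 6 libraries with over 20% of reads aligned to several places come from tests chosen only after the result was seen. Males with the Y haplotype B11 also had higher levels of the odorant-binding protein genes Obp83g and Obp99b, with log2 fold changes of 1.11 and 1.16, of the glutathione S-transferases GstE5 and GstZ2, at 0.52 and 0.50, and of Prx3, a peroxiredoxin of mitochondria, at 0.24. BomS6, of the Bomanin family of immune peptides, rose in B11 by 1.07 and in ZH23 by 0.77, and TotA, a Turandot stress gene, rose in ZH23 by 1.21. Cuticle genes moved both ways: Cpr62Ba at 1.15 and Cpr72Ec at 0.79 rose in B11, and Ccp84Ab at -1.35 and Cpr62Bc at -1.18 fell. All of these passed the test also without the 6 libraries, where Obp99b had 1.33 (adjusted p = 0.000692), BomS6 in B11 1.06 (0.000347) and TotA 1.17 (0.025).

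Other B38 calls of list members ended without those libraries. The eggshell genes Cp38 and Cp7Fb, which are not known to act in males, had log2 fold changes of 1.32 and 0.83 in all libraries and 0.16 and 0.24 without the 6, with adjusted p-values of 0.9 and 0.775. The neuronal genes elav, cac and Rdl went from 0.60, 0.49 and 0.44 to 0.44, 0.04 and 0.16, and the clock gene per from -0.76 to -0.82, with an adjusted p of 0.12. The immune genes DptA and IBIN kept their size, from 2.09 to 2.23 and from 2.29 to 2.52, with adjusted p-values of 0.057 and 0.0515.

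Genes of the mitochondrial genome, including its ribosomal RNAs, took 0.668% to 5.08% of the counts of a library. The 10 most abundant genes took 8.57% to 15.5%, and reads that overlapped no annotated gene were 2.27% to 6.50% of all reads. The share of reads aligned to several places had a median of 13.4% in replicate 1 and 11.4% in replicate 2, and at most 13.8% in batch 2.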
